A study of Mus musculus with 10 samples.

How the data were processed

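Array comparative genomic hybridization was used to compare tumour DNA with reference DNA in 10 low-grade astrocytomas, slowly growing glial brain tumours, dissected from the forebrain of mice. Each tumour was hybridized once, on 1 Agilent mouse oligonucleotide array with 2 colours. Per the labels, Cy5 carried the DNA of the tumour and Cy3 carried reference DNA pooled from the brains of 10 littermates, and every array had this orientation, so no dye swap was made. A positive log2 ratio therefore stands for more tumour than reference signal. The genotype labels define 3 groups, namely T with 3 tumours, TPhet with 6 and TPnull with 1. The label of 1 TPhet tumour is spelled Tphet and was counted as TPhet. Nothing in the labels expands T or P. Replicate numbers follow the order of the sample records and pair no tumours. The labels give each tumour its own animal number, so the spread between tumours of a group is a spread between animals.

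The scanner files hold intensity values for each spot. Per the file headers they were made with Agilent Feature Extraction version 10.7.3.1, with background subtraction, detrending and linear dye normalization, and probe coordinates refer to the mouse build mm8. The processed red and green intensity columns were used as deposited. The log10 ratio column of the same files was compared with the ratio of the processed intensity columns, per the file headers the same quantity, and was not used further. The authors also deposited a value table with log2 ratios of the same arrays, whose scale and centring are not stated in the sources used here. Against the scanner files its columns had medians between -0.003 and 0.003, correlated with the scanner log2 ratios across probes with r of 0.914 to 0.963, and had slopes of 0.786 to 0.904. Its direction was thereby taken as tumour over reference and its scale as slightly compressed, and the method behind it stays unknown. It was used as an alternative.

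Each array held 238202 spots that were not controls. Spots with an outlier mark in either channel were left out, between 165 and 270 per array, and spots of the same probe were averaged. Of 235402 distinct probes, 233212 lay on chromosomes 1 to 19, X and Y, and the other 2190 were not used. The autosomes held 220668 probes, with a median spacing of 7845 bp. The median raw signal was 8.12 to 11.6 times the median local background in Cy5 and 14.1 to 18.5 times in Cy3, and 99.6% to 99.9% of spots were well above background in both channels. The noise SD of an array, computed from the differences of neighbouring probes, ran from 0.160 to 0.336 on the log2 scale. The number of arrays limits the precision of every group mean. Each array's log2 ratios were centred on their autosomal median, with no loess or quantile normalization.

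Segments were found on each array by exact penalized least squares with pruning (PELT), with a penalty of 4 times the log of the number of probes on the chromosome times the noise variance and at least 10 probes per segment. A segment was called gained or lost at an absolute mean of 0.2 or more. The altered share was the percentage of autosomal probes inside called segments. Windows of 1 Mb with at least 10 probes (2386 windows) and genes with at least 2 probes (16395 genes, by the name in the scanner file) were summarised by the median of their probes. Of these names, 11940 were not only an accession, and 11845 of the 11940 matched a symbol or a unique synonym in a RefSeq table of assembly GRCm38.p6, from which names only were taken. A window counted as recurrent when called segments of the same direction in 2 or more tumours touched it. The number of recurrent windows was compared with 10000 random circular shifts of each tumour's calls along the joined autosomes. A locus is a chain of overlapping called segments, with the coordinates of its most frequent segment, and the 2 called gains of chromosome 3 in TPhet replicate 2 were kept out of the loci.

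All tumours were compared with the reference pool, and TPhet with T, with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, on windows and on genes. A call needed a Benjamini-Hochberg adjusted p under 0.05 and an absolute log2 value of 0.1 or more. In the genotype comparison the groups shared 1 estimate of the spread. The TPnull tumour had its own mean and added no residual, so this spread rests on the 9 T and TPhet tumours. Autosome medians were tested against 0 with an exact two-sided sign-flip permutation test over 10 tumours. The altered share was tested between 6 TPhet and 3 T tumours with an exact two-sided permutation test over all 84 splits. Other steps used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, numba 0.67.0, statsmodels 0.14.6 and matplotlib 3.10.9.

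These tests, 6 gene lists and the rule for naming genes were set before the data were examined. The rule takes the 10 largest gains and losses past the thresholds per gene comparison, or all that pass where fewer do, without names that are only an accession. A gene taken by this rule and a planned test of the probes of another gene are not reported here. The rule takes the 3 called segments per tumour with the highest absolute mean times the square root of the probes, and 2 to 4 members with the smallest p of each list. The lists are glioma tumour suppressors, glioma oncogenes, genome maintenance genes, glial and neural lineage genes, antigen receptor loci and gene families whose copy number varies between mouse strains. The last 2 lists take genes by the start of the name, so a single member of the strain-variable families need not vary itself. Genes and regions outside this rule were chosen after their values were seen. They are the shared loci, the gene of chromosome 10 in the genotype comparison, the genes that alternatives added to it, the single probes around Ide, the glioma genes given per tumour and Bub1b.

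The files give a scan time per array, which forms 3 scan batches of 5, 1 and 4 arrays. The labels word the reference pool in 2 ways, as whole brains of phenotypically wild-type animals for T replicate 1 and TPhet replicate 3 and as brains of syngeneic animals for the other 8. Both were used as batches, and T and TPhet tumours occur in scan batches 1 and 3 and in both wordings. The reference is a pool, so the spread between normal brains is not part of any test.

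The methods were tested on simulated data. On simulated arrays without planted segments, 0 segments were called at the lowest, the median and the highest noise SD. The simulated noise was normal and independent between probes, without single aberrant probes, so this count does not bound the false calls on the real arrays. Planted segments of 10 probes and a mean of 1 were found in 100%, 100% and 89.5% of cases at these 3 noise levels, and those of 10 probes and 0.5 in 94.7%, 0% and 0%. Planted segments of 50 probes and 0.3 were found in 100%, 26.3% and 0%, and those of 200 probes and 0.3 in 100% at each level. In simulated genotype comparisons with 200 planted changes, limma recovered 94.0% of the genes planted at 0.5 among 16395 genes, with 6 false calls in all, and 92.5% of the windows planted at 0.2 among 2386 windows, with 7 false calls. Smaller genotype changes were often missed, with 59.7% recovered of the genes planted at 0.25 and 47.8% of the windows planted at 0.1. In simulated comparisons with the pool it recovered 95.5% of the genes planted at 0.25, with 5 false calls, and 98.5% of the windows planted at 0.2, with 0 false calls. Unplanted genes and windows had a simulated mean of 0, without a constant dye or probe effect. The real comparison with the pool has no dye swap, so these low counts of false calls do not carry over to it.

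Alternatives covered the background correction (normexp with an offset of 50 on the raw signals), the authors' value table, the restriction to probes well above background in both channels, centring on the mode, removal of a trend of the log ratio on probe signal, the segmentation settings, the window size, the probe minimum of genes, the size minimum, the batch as a block, TPnull joined with TPhet and leaving out each tumour in turn. A correction for GC content needs the genome sequence of build mm8 and was not analysed here. No sample columns of other series occurred in the files.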

Results

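Copy number was measured in 10 mouse low-grade astrocytomas of 3 genotype groups, T with 3 tumours, TPhet with 6 and TPnull with 1. The comparisons addressed whether low-grade tumours hold copy number changes and whether these differ by genotype. Each tumour was hybridized once against a pool of 10 littermate brains, so values of a single tumour have no replicate. Probes had a median spacing of 7845 bp in build mm8, and the noise SD of an array ran from 0.160 to 0.336 on the log2 scale. P-values measure the spread between animals, apart from those of the circular shifts and of Fisher's test, which concern the placement of calls and counts of loci. The X chromosome had positive median log2 ratios of 0.28 to 0.40 in T replicates 1 and 2 and TPhet replicates 2 and 6, whose Y medians lay between -2.26 and -1.67. The other 6 tumours had X medians of -0.51 to -0.48 and Y medians of 0.42 to 0.68. The sex of a tumour mouse against the pool moves these medians, so they are not read as tumour gains or losses. The sex chromosomes were therefore kept out of all comparisons, and sex was not used as a covariate.

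Whole chromosomes departed from the reference pool in TPhet replicate 2. Its chromosome 3 had called gains at 3007185 to 94744879 (7097 probes, mean 0.31) and 94846657 to 159870361 (5910 probes, mean 0.29), and all 32 windows of 5 Mb along it were positive. Between the gains lay a called loss at 94752387 to 94837132 (10 probes, mean -0.52, median 0.017), which overlapped losses of 3 other tumours. The gains hold Sox2, a transcription factor of neural stem cells, Pik3ca, the catalytic subunit of a lipid kinase, the small GTPase gene Nras, the splicing and transcription regulator Fubp1, the progenitor filament gene Nes and the kinetochore motor gene Cenpe. The medians of chromosome 1 (0.17, positive in 40 of 40 windows) and chromosome 16 (-0.20, negative in 20 of 20 windows) also stood apart from the other tumours, though their segments did not reach the call threshold of 0.2. Lower values were found on chromosomes 9 (-0.11), 5 (-0.10), 11 (-0.10), 18 (-0.09), 19 (-0.09), 15 (-0.08) and 10 (-0.07). In the other 9 tumours no autosome median exceeded an absolute value of 0.0625, which 10 autosomes of TPhet replicate 2 did.

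**Figure D1:**
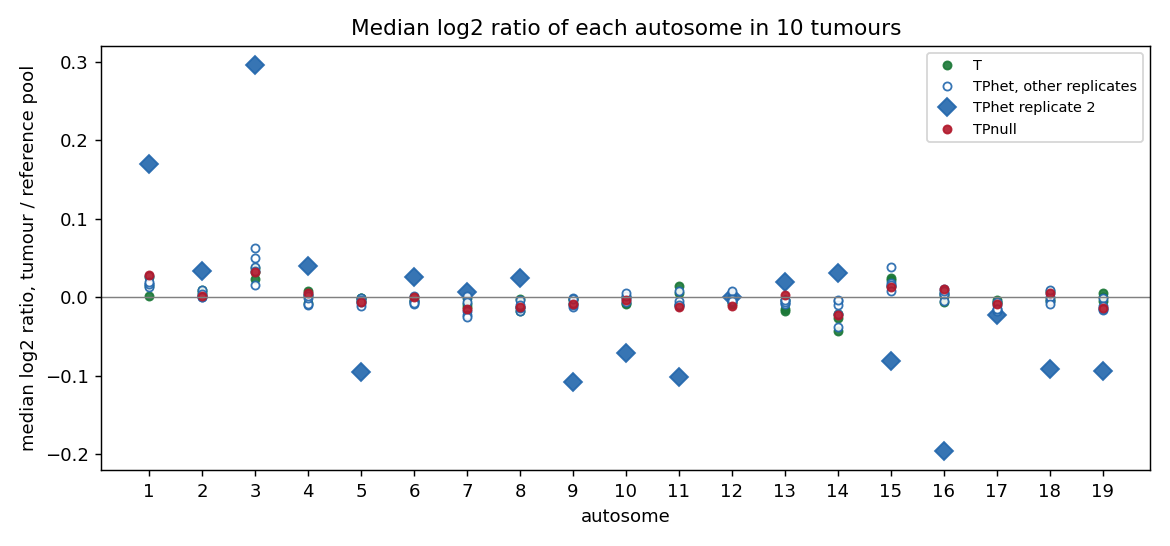
Median log2 ratio of each of the 19 autosomes (x axis) in each of the 10 tumours (y axis, tumour over reference pool), with TPhet replicate 2 as large diamonds. Chromosomes 3 and 1 of TPhet replicate 2 lie at 0.30 and 0.17 and chromosome 16 at -0.20, while all other tumours stay within 0.0625 of 0.

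Most called segments were short. In all, 225 segments were called on the autosomes, 42 gains and 183 losses, with a median length of 129 kb and 11 probes. Exactly 10 probes, the least allowed, made up 112 of them, and 12 exceeded 1 Mb, 8 of these outside TPhet replicate 2. No called segment outside TPhet replicate 2 held a gene of the glioma tumour suppressor or oncogene lists. Bub1b, a kinase of the mitotic spindle checkpoint, lay in a loss of TPhet replicate 1 at chromosome 2, 118169037 to 118376164 (28 probes, mean -0.47), whose median was only -0.13. A tumour had a median of 16 called segments, from 5 to 55, and a median altered share of 0.230% of autosomal probes. Without TPhet replicate 2 the median share was 0.2003%. Segment means can rest on few probes, and 155 of the 225 segments also had a median of at least 0.2 in absolute value.

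The 2 gains of chromosome 3 in TPhet replicate 2 held 406 and 385 named genes, and the other segments with the highest absolute mean times the square root of the probes held 0 to 5. Neto1, which encodes a glutamate receptor accessory protein, and Cbln2, a synaptic organizer, were lost together on chromosome 18 at 85257652 to 87804573 (205 probes), with medians of -1.08 in TPhet replicate 2, -0.78 in replicate 3 and -0.76 in replicate 6. Spock3, a brain proteoglycan gene, lay in a loss of T replicate 2 on chromosome 8 at 66123450 to 66213579 (11 probes, mean -1.45), whose median was only -0.21. Ugt1a10, a glucuronosyltransferase gene, was lost in T replicate 2 on chromosome 1 at 90044442 to 90133150 (16 probes, mean -0.99), and St6galnac1, a sialyltransferase gene, in T replicate 3 on chromosome 11 at 116545556 to 116597808 (10 probes, 6 of them well above background, mean -1.90), where TPhet replicate 1 had an overlapping loss (mean -0.47). Itlna, an intestinal lectin gene, and Cd244, a receptor gene of natural killer cells, were lost in TPhet replicate 4 on chromosome 1 at 173351486 to 173405431 (10 probes, mean -1.17). Loxl2, a collagen-crosslinking oxidase gene, and the mitochondrial iron carrier gene Slc25a37 lay in a loss of T replicate 1 on chromosome 14 at 68212568 to 68418241 (32 probes, mean -0.68), and overlapping losses had means of -0.81 in TPhet replicate 1, -0.72 in TPhet replicate 2 and -0.85 in the TPnull tumour. In the TPnull tumour the leading losses held no named gene and lay on chromosome 14 at 40173782 to 42577526 (10 probes, mean -1.72) and at 42820701 to 43281876 (10 probes, mean -2.05), inside losses of T replicate 3 (mean -0.37) and TPhet replicate 5 (mean -0.39).

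Many focal segments recurred, and often with the same boundaries. Of the 225 called segments, 147 overlapped a called segment of another tumour. With the 2 gains of chromosome 3 in TPhet replicate 2 left out it was 141, which formed 37 shared loci, 27 of them with identical boundaries in 2 or more tumours. Glo1, which detoxifies methylglyoxal, and its neighbours Btbd9, Dnahc8 and the incretin receptor gene Glp1r were gained on chromosome 17 at 30176354 to 30650272 (66 probes), with medians of 0.50 to 0.55 in T replicate 2 and TPhet replicates 2 to 6. A region without a named gene on chromosome 2 at 77680396 to 77822062 (13 probes) had medians of 2.59 to 2.63 in TPhet replicates 2, 3, 5 and 6. Genes of the Skint family of keratinocyte selection proteins on chromosome 4, around 111551341 to 112104237, were gained in the TPnull tumour (47 probes, mean 1.08), TPhet replicate 5 (mean 1.10) and T replicate 1 (mean 0.68). The same genes were lost in T replicate 3 (mean -2.95) and in TPhet replicates 1 (mean -2.75) and 3 (mean -2.97), where 19 of 44, 12 of 29 and 13 of 32 probes were well above background, so these losses are bounds on the true ratio. Gains in some tumours and losses in others occurred at 5 of the 37 loci, among them the Itlna and Cd244 locus, with 0.69 in TPhet replicate 1 against -1.22 to -1.14 in TPhet replicates 4 and 6 and the TPnull tumour. Tumours of both T and TPhet were called at 13 loci. Natural killer receptor genes (Klra22, Klra17, Klra5) on chromosome 6, inflammasome genes (Nalp1b, Nalp1c) on chromosome 11 and cytochrome P450 genes (Cyp2c38, Cyp2c39, Cyp2c29) on chromosome 19 were further shared loci.

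Recurrence exceeded what random placement gave. Called segments of the same direction in 2 or more tumours touched 43 of 2386 windows of 1 Mb, against a median of 9 and a maximum of 25 over 10000 circular shifts (one-sided permutation p = 0.0001, the smallest possible). For 3 or more tumours the count was 27, against a median of 0 and a maximum of 4. Windows with gains and losses in different tumours numbered 16, against a median of 21 in the shifts (one-sided permutation p = 0.897). All called segments were shifted, also the 2 gains of chromosome 3 in TPhet replicate 2. Losses of other tumours can fall on these long gains in the shifts, so this count does not test focal loci alone. Genes of the list of families whose copy number varies between mouse strains, taken by the start of the name, were present at 10 of the 37 shared loci and at 12 of 82 loci of 1 tumour, a difference that did not pass Fisher's exact test (two-sided p = 0.129). The count of recurrent windows ranged over alternatives from 15 with single windows called without segmentation to 109 with a penalty factor of 2.

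**Figure D2:**
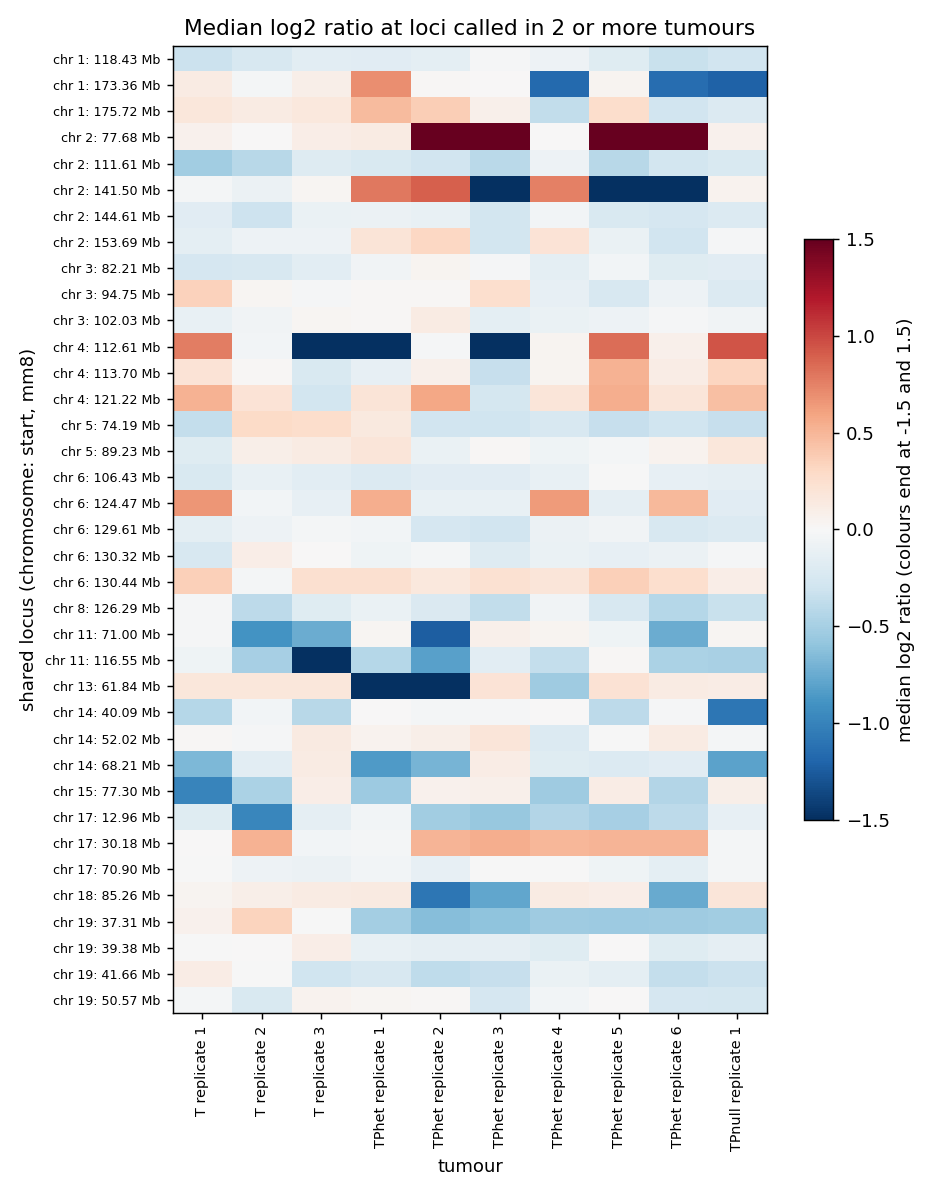
Median log2 ratio (colour, ending at -1.5 and 1.5) of the 37 shared loci (y axis, by chromosome and start) in the 10 tumours (x axis). The chromosome 17 locus at 30176354 is gained in 6 tumours, the chromosome 18 locus at 85257652 is lost in 3, and the chromosome 2 locus at 77680396 is gained in 4.

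Altered shares were compared between genotypes to ask whether TPhet tumours carry more copy number change than T tumours. The 3 T tumours had altered shares of 0.110%, 0.0856% and 0.0725% (0.0893% ± 0.0188, SD, n = 3). The 6 TPhet tumours had 0.271%, 6.24%, 0.2003%, 0.377%, 0.175% and 0.261% (1.25% ± 2.44, SD, n = 6), and the TPnull tumour had 0.294%. Each T tumour lay below each TPhet tumour, but the difference of means, 1.16 percentage points, was within the spread (exact permutation p = 0.345, two-sided, where 84 splits allow no p below 0.0119). TPhet replicate 2 decided the size of this difference, which was 0.168 percentage points without it (exact permutation p = 0.0357). On ranks, a test chosen after seeing the data, the difference of 4.5 mean ranks had an exact permutation p of 0.0238. In segments of 1 tumour, also chosen after, it was 0.0786 percentage points (exact permutation p = 0.131), with T replicate 2 (0.0267%) above TPhet replicates 3 (0.00453%) and 5 (0.0218%). The difference was 2.16 in scan batch 1 and 0.185 in scan batch 3 (1 T and 3 TPhet tumours each), while batch 2 held 1 T tumour only. Within the wordings of the reference pool it was 1.39 (2 T and 5 TPhet tumours) and 0.0906 (1 of each). With normexp background correction T replicate 2 rose to 0.379%, above 5 of the 6 TPhet tumours (exact permutation p = 0.738). With the signal trend removed T replicate 2 had 0.403%, above 4 TPhet tumours, without segmentation T replicate 1 had 0.180%, above 4, and at a threshold of 0.1 each T tumour lay above TPhet replicate 6 (0.261%). Called segments numbered 8.33 ± 3.06 (SD, n = 3) in T and 27.5 ± 17.6 (SD, n = 6) in TPhet (exact permutation p = 0.0952), and the noise SD of the arrays averaged 0.289 in T and 0.248 in TPhet.

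**Figure D3:**
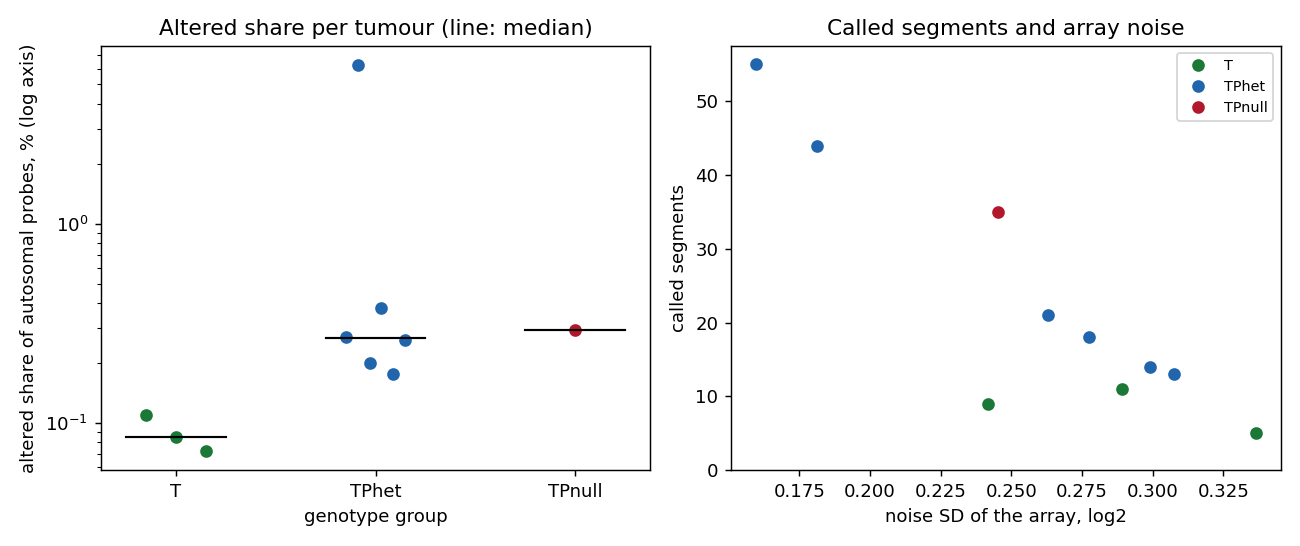
Altered share of autosomal probes per tumour by genotype on a log axis (left, lines are medians) and called segments against the noise SD of the array (right), 1 point per tumour. The T tumours lie between 0.0725% and 0.110%, the TPhet tumours between 0.175% and 6.24%, and the quietest arrays, TPhet replicates 4 and 1, have 55 and 44 called segments.

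Small shifts of whole chromosomes and regions against the reference pool were shared by most tumours. No array had swapped dyes and no GC correction was run, so a constant effect of dye or probes can add to each of these shifts. Chromosome 3 (mean 0.062 ± 0.083, SD, n = 10) and chromosome 1 (mean 0.033 ± 0.049, SD, n = 10) were higher than the pool in 10 of 10 tumours, and chromosomes 5, 9 and 17 were lower in 10 of 10 (exact sign-flip permutation p = 0.00195, the smallest possible, adjusted p = 0.00742). With chromosomes 2 (higher in 9 tumours), 7 (lower in 8) and 19 (lower in 9), 8 of the 19 autosomes passed. Without TPhet replicate 2, 13 autosomes passed, and the mean was 0.036 for chromosome 3 and 0.018 for chromosome 1. With limma over the autosomes 1 passed, and with the mean of the probes 3 did. Among windows of 1 Mb, limma called 55 of 2386, 42 higher and 13 lower than the pool, 25 of them on chromosome 3. Without TPhet replicate 2 the count was 35, and with the scan batch or the pool wording as a block it was 53 or 59. The highest were chromosome 4 at 121000001 to 122000000 (0.23, SE 0.054, adjusted p = 0.00435, higher in 8 of 10), chromosome 1 at 5000001 to 6000000 (0.18, SE 0.019, adjusted p = 3.4e-05, higher in 10 of 10), and the lowest was chromosome 7 at 39000001 to 40000000 (-0.13, SE 0.013, adjusted p = 2.6e-05, lower in 10 of 10). The split of higher and lower calls moved with the scaling, to 33 and 3 in the authors' value table, 107 and 5 with centring on the mode, 48 and 5 with normexp and 41 and 3 with the signal trend removed. Window size set the count too, with 276 calls at 0.5 Mb and 4 at 5 Mb.

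Gene medians differed from the pool for many genes. Gcat, of threonine breakdown, was higher by 0.71 (SE 0.068, limma adjusted p = 2.1e-06, n = 10), and so were Bcat2, of branched-chain amino acid breakdown (0.69), the steroid dehydrogenase gene Hsd3b3 (0.65), the peroxisomal fatty acid reductase gene Decr2 (0.62), Tmem153, now Lmf2, a lipase maturation factor (0.60), the secreted protease gene Clca1 (0.58), Glp1r (0.58), Gm71, now Vcpkmt, a methyltransferase gene (0.57) and Commd2 (0.57). Dgcr6, from the region deleted in DiGeorge syndrome, was lower at -0.69 (SE 0.039, limma adjusted p = 9.3e-08, n = 10), as were the zinc finger gene Zfp579 (-0.66), the neural homeobox gene Barhl2 (-0.61), 9230105E10Rik, now Trim12c (-0.59), the perineuronal link protein gene Hapln4 (-0.57), 2610203E10Rik, now Accs (-0.56), Ccdc32 (-0.56), the thyroid hormone activating enzyme gene Dio2 (-0.52) and Jsrp1, of the sarcoplasmic reticulum (-0.52). All of these had the same direction in 10 of 10 tumours. Gm156, now the natural killer receptor gene Klrh1, had the lowest mean at -0.81 (limma adjusted p = 0.0113) but was lower in 7 tumours and higher in 3, and it was at -0.28 on probes well above background and -0.21 with normexp, where Dgcr6 was lower (-0.69 and -0.55). Probes within 100 kb of these genes had means from -0.099 to 0.12, with 0.028 beside Gcat and -0.053 beside Dgcr6, except for 0.19 beside Glp1r, which lies in the shared gain of chromosome 17. In total limma called 6933 of 16395 genes, 3638 higher and 3295 lower, and with centring on the mode 4382 were higher and 2633 lower. Values depended on the processing, and with normexp Bcat2 was at 0.12, Decr2 at 0.22, Tmem153 at 0.23 and 9230105E10Rik, no longer called, at -0.072. On probes well above background 9230105E10Rik was at 0.0072, in the opposite direction. No array had swapped dyes, so a constant dye effect of a probe adds to each of these values.

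Genes of the 6 lists were called against the pool beside 6933 of 16395 genes in all, and most tested glioma genes did not pass. The called shares of the glioma lists, 7 of 19 and 13 of 32, lay near that share of all genes. Without a dye swap, a constant dye or probe effect adds to each value below. The values do not by themselves show a copy number change of a listed gene. Of 19 tested glioma tumour suppressors, limma called 3 higher and 4 lower, and 12 did not pass. Tsc2 was lower (-0.25) and its partner in restraining mTOR signalling, Tsc1, higher (0.16), as was the cyclin-dependent kinase inhibitor Cdkn2c (0.19). Of 32 oncogenes 19 did not pass, 4 were higher, among them the p53 inhibitors Mdm2 (0.45) and Mdm4 (0.20), and 9 lower, among them the hedgehog effector Gli1 (-0.32) and the endothelial receptor Kdr (-0.19). Genome maintenance genes gave 5 higher and 2 lower of 23, with the spindle checkpoint gene Mad2l1 at -0.22, the mismatch repair gene Msh6 at -0.13, Brca1 at 0.14 and Aurkb at 0.15. Glial and neural lineage genes gave 4 higher and 2 lower of 12, with the astrocyte genes Aldh1l1 at -0.29, Aqp4 at 0.27, Vim at 0.24 and S100b at 0.16. Families that vary between strains gave 91 higher and 73 lower of 362, with the zinc finger genes Zfp526 at 0.29, Zfp352 at 0.27, Zfp740 at 0.27 and Zfp371 at 0.27. All names starting with Zfp entered this list, so these zinc finger genes need not vary between strains themselves. Only Ighmbp2, a helicase gene caught by the name prefix and not a receptor gene, was tested among antigen receptor loci, and it was not called (0 genes, also at an unadjusted p under 0.05). Adjusted over the list alone, these 6 counts were the same, namely 7, 13, 7, 6, 164 and 0. With normexp the signs of Terf1 (-0.068), Mog (-0.015), Rbl2 (-0.049) and 22 called genes of the strain-variable families were opposite, and Msh6 (-0.0072), Brca1 (0.035), Aurkb (0.013), Mdm4 (0.089), Zfp352 (0.084) and Zfp740 (0.081) were not called. Still called with normexp were Mdm2 at 0.14, Tsc2 at -0.14 and Aqp4 at 0.15, while Vim (0.33) and Gli1 (-0.42) lay farther from 0 than before. Mdm2 was at 0.32 in the authors' value table and with the signal trend removed. Of the 7 genome maintenance calls normexp kept 1, with 2 higher and 2 lower in all. In the strain-variable families 4 called genes had the opposite sign in the authors' value table and 7 with the signal trend removed. For genome maintenance the value table gave 0 higher and 2 lower and kept 1 of the 7 calls, without Brca1 (0.094), Msh6 (-0.077) and Aurkb (0.019). Removal of the signal trend kept 3 of them, without Msh6 (-0.066) and Aurkb (0.087), and centring on the mode gave 7 higher and 2 lower.

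Ide, the gene of insulin-degrading enzyme and a gene of the strain-variable families, was the largest called difference between TPhet and T. Over its 10 probes at chromosome 19, 37335774 to 37394328, TPhet lay at -0.52 and T at 0.23, a difference of -0.75 (SE 0.067, limma adjusted p = 0.00179, n = 6 and 3). The T tumours had 0.15, 0.42 and 0.12, each TPhet tumour lay between -0.61 and -0.46, and the TPnull tumour had -0.46. The call held in 22 of 22 settings, with limma adjusted p from 0.000312 to 0.0163 and differences from -0.83 to -0.65. Among these settings, leaving out the TPnull tumour only repeats the reported values, since that tumour adds no residual. It was -0.79 with the scan batch as a block (adjusted p = 0.00392) and -0.77 with the pool wording as a block (adjusted p = 0.00247). Within scan batches 1 and 3 the difference was -0.67 and -0.90, and within the wordings -0.78 and -0.74. Another gene, known in the files by an accession only, was called on chromosome 10 at 21764131 to 21786307 (2 probes, TPhet -0.11, T -0.54, difference 0.43, SE 0.054, limma adjusted p = 0.0323) and is named here after its values were seen. It was 0.37 within scan batch 1, 0.42 within batch 3, and 0.37 and 0.60 within the wordings, but its call ended with the scan batch (0.39, adjusted p = 0.367) or the pool wording (0.43, adjusted p = 0.0840) as a block and with normexp (0.22, adjusted p = 0.814). Its call also ended without T replicate 1 or 2 or any of TPhet replicates 1, 2, 3, 5 and 6, with adjusted p from 0.0783 to 0.428. Limma called these 2 of 16395 genes (1188 at an unadjusted p under 0.05), and with the mean of the probes it called 3, with another gene known by an accession only on chromosome 10 at 21812195 to 21837692 (5 probes, 0.38, adjusted p = 0.0163). Without T replicate 3 it called 5, with Thtpa (-0.49), 1810013C15Rik (-0.36) and 6430571L13Rik (-0.34) added.

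Among windows, limma called 0 of 2386 between TPhet and T, with 118 at an unadjusted p under 0.05. The smallest p belonged to chromosome 19 at 37000001 to 38000000, the window of Ide (-0.16, SE 0.029, adjusted p = 0.525). That window was called with the mean of the probes (-0.20, adjusted p = 0.00709), with the signal trend removed (-0.15, adjusted p = 0.0161) and without TPhet replicate 2 (-0.14, adjusted p = 0.0186). With the scan batch or the pool wording as a block 0 windows were called, with 19 and 72 at an unadjusted p under 0.05. Of the 5 lists other than the strain-variable families, limma called 0 genes between TPhet and T, also adjusted over the list alone, and 1, 1, 2, 0 and 0 genes had an unadjusted p under 0.05 among tumour suppressors, oncogenes, genome maintenance, lineage genes and antigen receptor loci. These were the retinoblastoma relative Rbl1 (0.09), the cyclin gene Ccnd2 (-0.21, limma adjusted p = 0.682, and 0.107 adjusted over the list alone), the DNA repair gene Parp1 (0.11) and Cenpe (0.15), and the differences of all 4 failed the adjustment. In the strain-variable families 1 gene was called, Ide, also adjusted over the list alone, 26 had an unadjusted p under 0.05, and Cyp2c39 at -0.30 came next.

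**Figure D4:**
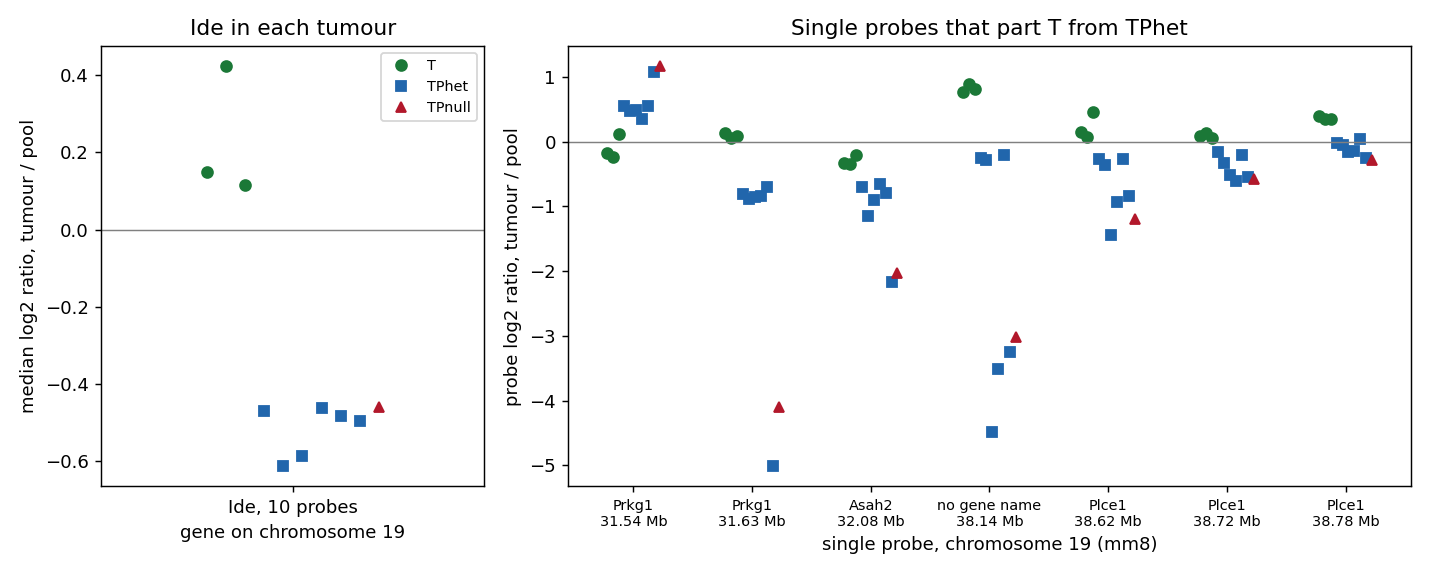
Median log2 ratio of Ide (10 probes) in each tumour (left) and log2 ratio of 7 single probes on chromosome 19 more than 500 kb from the Ide locus (right), 1 mark per tumour and genotype group by colour. At Ide the T tumours lie at 0.12 to 0.42 and all others at -0.61 to -0.46.

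Outside called segments, the glioma genes farthest from the median of the 10 tumours were Pdgfa, a ligand of the growth factor receptor gene Pdgfra, with 0.51 in T replicate 1, and Ccnd2 with 0.30 in the same tumour. Trp53 had -0.40 in TPhet replicate 2 and Mdm2 had 0.18 in TPhet replicate 4 against a median of 0.48. Pdgfa, Trp53 and Mdm2 had 3 probes each and Ccnd2 had 4, and each of these values comes from 1 array. T replicate 1 had the highest noise SD (0.336) and TPhet replicate 4 the lowest (0.160), so changes particular to these tumours cannot be read from them. The cell cycle inhibitor gene Cdkn2a stayed between -0.07 and 0.08, the Ras regulator gene Nf1 between 0.0094 and 0.10, and the receptor gene Egfr between -0.22 and -0.0054.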

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

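Apart from the circular shifts, all tests of explanations in this part were chosen only after the result was seen.

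TPhet replicate 2 lay far from the other 5 TPhet tumours in 16 of 27 measures, where chance alone marks about 1 group in 20. They were its altered share of 6.24%, with the next tumour at 0.377%, and the medians of 15 autosomes. Chromosomes 3 (0.30), 1 (0.17), 4 (0.039), 2 (0.033), 6 (0.025), 8 (0.024) and 13 (0.019) lay above the other TPhet tumours, and chromosomes 16 (-0.20), 9 (-0.11), 11 (-0.10), 5 (-0.096), 19 (-0.094), 18 (-0.091), 15 (-0.081) and 10 (-0.072) lay below them. The 15 medians share 1 array and its centring, so they are not independent.

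Array noise, a trend with probe signal and a wave shared by all arrays were weighed for the chromosome shifts of TPhet replicate 2. The 2 arrays with a higher noise SD had no autosome median beyond 0.0497 in absolute value, chromosome 3 kept a median of 0.30 once the signal trend was removed, and chromosome 15 was at -0.081 here but at 0.0079 to 0.039 in all other tumours, which argue against noise, trend and a shared wave as the whole cause. Across the 19 autosomes the medians of this tumour and the mean of the other 9 had r of 0.496 and rho of 0.146, just under the bound of 0.5 set for the wave, and autosomes are not independent replicates. A candidate explanation is gain of chromosomes 3 and 1 and loss of chromosome 16 and others in part of the cells of this tumour, a hypothesis found on the same array, for which no biological explanation was tested.

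Focal segments at the same place in several tumours were weighed as inherited differences between the mice, as isolated aberrant probes and as chance placement. Chance placement is excluded by the circular shifts (one-sided permutation p = 0.0001, the smallest possible). Of 249 overlapping pairs of segments of different tumours, 81 (32.5%) had both ends at the same probe, between the bounds of 50% set for inheritance and 10% set for separate breaks. Identical ends alone do not separate inheritance from isolated probes. At chromosome 3, 102031090 to 102125714, 3 tumours had a called loss of the same 10 probes, while the medians of all tumours lay between -0.14 and 0.13. Of 141 shared segments, 109 (77.3%) had a median past the call threshold, under the bound of 80% that would exclude isolated probes, against 44 of 82 (53.7%) segments of 1 tumour. A median past the threshold needs more than a few aberrant probes, so it argues against isolated probes as the whole cause of these 109 segments. An example is the chromosome 18 loss at 85257652, with 205 probes and medians of -1.08, -0.78 and -0.76 in TPhet replicates 2, 3 and 6. In the other shared segments inherited copy number and isolated probes cannot be told apart. Whether shared changes were inherited or arose in the tumours stays open, because the reference is a pool and no normal tissue of the same mice was analysed here.

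Ide differed between the genotypes, by -0.75 in TPhet against T, with the TPnull tumour on the TPhet side. The lowest T tumour lay above the highest TPhet tumour by at least 0.59 within scan batches and 0.58 within pool wordings, against a range of 0.15 among TPhet tumours, which argues against both batches. All 10 of 10 Ide probes had each T tumour above each TPhet tumour, which argues against base changes under single probes. Within 10 Mb of Ide and outside its segment 14 of 2190 probes separated T from TPhet by 0.2 or more without overlap (0.639%, against 0.0177% of 214377 probes on other autosomes), only 1 of the 84 splits, the real one, gave as many (the highest other gave 13), and the TPnull tumour was nearer to TPhet at 14 of 14 (32 of 38 on other autosomes), but beyond 500 kb of the Ide locus 3 of the 84 splits gave as many as the real 7. A haplotype around Ide that differs between the genotypes could account for it, as a hypothesis with a narrow margin over the next split, while a somatic change selected with the genotype stays open and untested.

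The other gene that differed between the genotypes, known by an accession only, lay on chromosome 10 and differed by 0.43 between TPhet and T. For the genes, 8 of the 84 splits of the 9 tumours gave 2 or more calls, so chance cannot be excluded for the count of 2, and the highest other split, TPhet replicates 1 and 4 with T replicate 3 against the rest, gave 15, several times the real count, which may reflect a structure of these samples other than genotype, though whether 15 exceeds chance was not tested. Those 3 arrays had the lowest noise SD of the 9 (0.160 to 0.242). For the windows the real count was 0, which 84 of 84 splits reach by construction, so the splits decide nothing there, and the highest other split gave 3.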

How the results depend on the processing

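The tests on segment medians, on segments of 1 tumour and on ranks of the altered share were chosen only after the result was seen. No paired analysis was possible because replicate numbers follow record order and pair no tumours. A correction for GC content was not run. Called segments, 225 as reported, numbered 133 with normexp, 102 on probes well above background, 88 and 499 with penalty factors of 8 and 2, and 339 with at least 5 probes. Recurrent windows, 43 as reported, numbered 26 on probes well above background, 76 with the signal trend removed, 90 at a threshold of 0.1, 17 and 109 with penalty factors of 8 and 2, 15 without segmentation and 27 for 3 or more tumours, and the one-sided permutation p over all alternatives ran from 0.0001, the smallest possible, to 0.0339. Altered shares of single tumours, 0.0725% to 6.24% as reported, ran from 0.261% to 26.3% at a threshold of 0.1. With a penalty factor of 8 they ran from 0.0421% to 6.07%. The altered share differed between TPhet and T past the threshold on ranks (4.5, exact permutation p = 0.0238) and without TPhet replicate 2 (0.168, exact permutation p = 0.0357), with p over alternatives from 0.0238 to 0.738. Autosomes called against the pool, 8 as reported, numbered 5 with normexp, 5 in the value table, 5 with the trend removed, 3 with the mean of the probes and 1 with limma. Windows against the pool, 55 as reported, numbered 36 in the value table, 112 with centring on the mode, 276 at 0.5 Mb, 4 at 5 Mb, 997 with no size minimum and 1 with a minimum of 0.2. Genes against the pool, 6933 as reported, numbered 12474 with at least 1 probe, 2196 with at least 5, 10434 with no size minimum and 2351 with a minimum of 0.2. Between TPhet and T, 1 window was called with the trend removed and 1 with the mean of the probes, and 1 gene, Ide, with normexp, with the pool wording as a block, with the scan batch as a block and with at least 5 probes, while with at least 1 probe Ide and Fgfbp3 (-0.75) were called.

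Leaving out each tumour in turn gave 170 to 220 called segments, a median altered share of 0.2003% to 0.261%, a share difference of 0.168 to 1.38, 35 to 43 recurrent windows, 6 to 13 autosomes and 35 to 79 windows against the pool, 0 to 1 windows between TPhet and T, 6672 to 7300 genes against the pool and 1 to 5 genes between TPhet and T. Without TPhet replicate 2 there were 13 autosomes, 35 windows against the pool and 1 between the groups, and without T replicate 3 there were 5 genes. Where a T tumour was left out, limma pooled the spread of all groups. Of the named genes, 366 of 378 alternatives kept direction and call, 11 lost the call and 1 reversed, 9230105E10Rik on probes well above background (0.0072), and the cause was not tested. Over their reported coordinates, named segments kept their direction and an absolute mean of at least 0.2 in 149 of 150 alternatives. The arrays were not segmented anew for this count, so it does not show that each segment would be called again. The medians of 10 chromosomes of TPhet replicate 2 kept their direction in 50 of 50, with chromosome 3 from 0.30 to 0.40. Signal over background limits deep losses, since Cy5 signal was 8.12 to 11.6 times background and probes not well above it give only a bound. The causes of the other changes were not tested.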

Other observations

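The test of the noise relation was chosen only after the result was seen, as were the counts of separating probes.

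Genes around Ide on chromosome 19 divided the tumours at single probes. At a probe in Prkg1, the gene of a cGMP-dependent kinase, at 31543576, T tumours had log2 ratios of -0.24 to 0.12, TPhet tumours 0.35 to 1.07 and the TPnull tumour 1.17. At another Prkg1 probe, at 31630691, T tumours had log2 ratios of 0.05 to 0.13, while 5 TPhet tumours had -0.89 to -0.70, TPhet replicate 6 had -5.01 and the TPnull tumour had -4.10. At a probe in the ceramidase gene Asah2 at 32083272, TPhet replicate 6 (-2.16) and the TPnull tumour (-2.02) again lay below the other TPhet tumours (-1.15 to -0.66) and the T tumours (-0.35 to -0.21). Beyond Ide, at a probe without a gene name at 38144363, TPhet replicates 3, 4 and 6 and the TPnull tumour had -4.49 to -3.02, TPhet replicates 1, 2 and 5 had -0.29 to -0.21, and the T tumours had 0.77 to 0.89. The deepest ratios, here and at Prkg1, may be only bounds on the true ratio, since the median Cy5 signal was 8.12 to 11.6 times background. Probes in the phospholipase gene Plce1 at 38618215, 38720298 and 38783251 also separated T from TPhet. More than 500 kb from the Ide locus 7 of 2102 probes within 10 Mb of Ide separated the groups, 3 of the 84 splits, with the real one, gave as many, and the highest other gave 13.

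Probes that separated T from TPhet outside chromosome 19 were most frequent on chromosome 10 at 20000001 to 25000000, with 12 probes, in the region of the called gene of chromosome 10. Over all of chromosome 10, 5 of the 84 splits gave as many separating probes as the real 15, and the highest other gave 32. Chromosome 19 at 35000001 to 40000000 had 27, a count that includes the Ide segment and so is no support apart from Ide. Outside that segment 14 probes within 10 Mb of Ide separated the groups.

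Arrays with less noise had more called segments over the 10 tumours (r = -0.898, permutation p = 0.0006, adjusted p = 0.0012, and rho = -0.709, permutation p = 0.0265, adjusted p = 0.0529, for 2 relations). The penalty of the segmentation rises with the same noise variance, so this relation is in part built into the calling. Its p-values are therefore no independent evidence. Without TPhet replicates 1 and 4, the arrays farthest from the median noise, r was -0.604 and rho was -0.429. Noise and altered share had r = 0.214 (permutation p = 0.505, adjusted p = 0.505) and rho = -0.236 (permutation p = 0.513, adjusted p = 0.513). TPhet replicate 2, with an altered share of 6.24% at a noise SD of 0.299, lay far from the other tumours and weighs on this r. The relation without TPhet replicate 2 was not computed, so these values do not show that the altered share is free of array noise. Within the 8 arrays of the first pool wording, noise and called segments had r = -0.882 (exact permutation p = 0.00583) and rho = -0.619 (exact permutation p = 0.115), and noise and altered share had r = 0.409 (exact permutation p = 0.369) and rho = -0.024 (exact permutation p = 0.977). The scan batches and the second wording held at most 5 arrays, under the minimum of 6 set for a correlation. The count of called segments per tumour may follow the noise of the array (rho = -0.709, and -0.429 without the 2 arrays) as well as the tumour, and it is no measure of alteration between genotypes by itself.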
